A study of Mus musculus with 48 samples.

How the data were processed

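Striatal RNA was measured by RNA-seq in 48 mice of 6 genotypes, with 8 mice per genotype and 4 of each sex. The genotypes were wild type (WT), Q140, the Msh3+/- and Msh3-/- genotypes without Q140, and the Q140 crosses Q140 x Msh3-/- and Q140 x Msh3+/-. Q140 is a knock-in mouse model of Huntington's disease in which the mouse Htt gene carries an expanded CAG repeat; the labels give the Q140 mice as heterozygous, so that 1 Htt allele carries it. Msh3 encodes a DNA mismatch repair protein. Groups, sexes and replicate numbers were taken from the sample titles. Per the labels, each sample is the striatum of a separate mouse on a C57BL/6 background. The labels give an age of 12 months, while the extraction text in the same labels speaks of dissection at 6 months, so the age at dissection is uncertain. Libraries were stranded TruSeq preparations, per the labels' protocols.

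The authors deposited a table of whole-number counts per gene, with 48795 genes and a column per library, and a table of FPKM values for the same genes. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10, HTSeq 0.12.3 and the mouse build GRCm38 (mm10). The gene annotation release, the strand setting of the counting and any filter are not given in the sources used here. The deposited counts were not normalized: library totals ranged from 38.9 M to 60.9 M (M, 1e6 counts) with a median of 47.3 M. Each deposited FPKM value equalled the count times a constant per gene divided by the library total, with a largest relative deviation of 4e-07 over the 19144 genes compared, so the FPKM table holds no measurement beyond the counts. All columns were matched to samples by name. In the table, 27 gene symbols had been turned into dates and were restored from their Ensembl identifiers. Of the identifiers, 48349 were found in GENCODE M21 for GRCm38, which gave coordinates, and 446 were not. Counts of close paralogs such as the clustered protocadherins, of overlapping genes and of antisense genes depend on the counting settings and are uncertain to that extent.

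Genes were kept when they passed edgeR's filterByExpr by group (minimum count 10), which left 19714 genes tested and 29081 filtered out. Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, robust dispersion estimation and the quasi-likelihood F-test in a fit of all 48 libraries, with the 6 genotypes and sex as terms and 41 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All adjusted p-values given for genes are from this test unless another is named, and all fold changes are on the log2 scale with their standard error (SE). Levels are TMM-scaled counts per 1e6 counts (CPM), given as mean ± SD with n = 8. The 10 contrasts were Q140 minus WT, Msh3+/- and Msh3-/- minus WT, each Q140 cross minus Q140, the Q140 crosses against each other, each Q140 cross minus its own Msh3 background, and an interaction for each Msh3 genotype, which is the Q140 effect on that background minus the Q140 effect on the WT background. Sex differences of the Q140 effect and of the Q140 x Msh3-/- effect were tested in a fit with a term for each genotype and sex. Gene lists were tested with camera (limma 3.58.1), with an inter-gene correlation preset to 0.01 and again with the correlation estimated. Camera p-values were adjusted over the lists within a contrast.

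Reversal of Q140 changes was counted as genes past the threshold in Q140 minus WT that also passed it with the opposite sign in a Q140 cross minus Q140. Both contrasts hold the same 8 Q140 libraries, which alone favours opposite signs. The count is therefore given beside the mean of 10 simulated data sets with no change between the Q140 groups. In these each gene was drawn independently around its fitted mean, so structure shared across genes is missing. The count is also given beside the number with opposite signs expected of independent lists. A last comparison is with 10 analyses in which 4 Q140 mice served each contrast. A signature score per mouse avoided the sharing: signature genes and signs were called in 4 Q140 against 4 WT mice, only the other mice were scored with them as the mean signed log2 CPM, and the score was averaged over 20 such splits and their mirrors. Signatures held a median of 3725 genes (range 2923 to 4545). Scores were compared with 2-sided exact permutation tests over 12870 arrangements, adjusted over 8 comparisons. The smallest p these can give is 0.000155. The share reversed is the score difference between Q140 and a cross divided by that between Q140 and WT, with a 95% bootstrap interval over mice (10000 draws).

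The named genes follow a rule: Msh3 and Htt; all genes past the threshold where there were 20 or fewer; otherwise the 8 with the largest rise and the 8 with the largest fall among those past the threshold with a mean log2 CPM of at least 1; and from each gene list with several members past the threshold, the up to 4 with the smallest adjusted p. Some genes that the rule names are not reported here. Groups, gene lists, tests, the naming rule and most alternatives were fixed before the data were examined. Lists of all tested genes within 5 Mb of Msh3 or Htt were built from the annotation.

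The functions were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes among 19714. The changed genes were drawn only from genes with mean counts well above the filter's minimum. Recovery among low-count genes was therefore not simulated. For Q140 minus WT, 92 of 100 genes changed by 0.5 on the log2 scale and 99 of 100 changed by 1 were called, with 10 false calls. For Q140 x Msh3-/- minus Q140, 61 of 100 genes changed by 0.25 and 92 of 100 changed by 0.5 were called. For the Msh3-/- interaction, 35 of 100 changed by 0.25 and 82 of 100 changed by 0.5 were called. A simulated reversal of 50% gave a score share of 49.9%. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 15.7), so all 48 were counted separately.

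The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its Wald test, no low-count filter, only the groups of a contrast, no sex term, a block of sex and replicate number, the plate's well column as a term, an adjusted p under 0.10, limma on log2(FPKM + 0.1), the data without the 2 WT mice whose sample names have another prefix, and each mouse left out in turn. Alternatives chosen after seeing the data were total counts in place of TMM, the data without 4 libraries that stood apart on the first component of the residuals, without Q140 mouse F1, without genes within 5 Mb of Msh3 or Htt, and the prefix of the sample names as a term in edgeR or as a random effect in limma-voom. There were 27 prefixes, 12 of them with several libraries (33 in all), and what they stand for is not given in the labels. As a term they left 15 residual degrees of freedom and took up the 15 libraries alone in their prefix. Figures were drawn with matplotlib 3.10.9.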

Results

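The striatum, the brain region most affected in Huntington's disease, was profiled by RNA-seq in 48 mice: WT and heterozygous Q140 mice, and mice of either kind with 1 or both Msh3 alleles lost by their labels (Msh3+/-, Msh3-/- and the Q140 crosses with each), with 8 mice (4 of each sex) per genotype. Counts per library averaged between 44.49 ± 3.56 M in Msh3-/- and 49.09 ± 2.88 M in Q140 mice (SD, n = 8). The design asks what the Q140 allele does to striatal transcription, what loss of Msh3 alleles does by itself, and whether loss of Msh3 changes the Q140 effect.

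Msh3 (ENSMUSG00000014850; GRCm38 chromosome 13, 92211872 to 92355003, minus strand) was the targeted gene, and its RNA was examined first. Its level rose with each allele labelled as lost. It was 28.97 ± 1.61 CPM in WT, 73.94 ± 1.56 CPM in Msh3+/- and 122.4 ± 3.1 CPM in Msh3-/- mice (SD, n = 8 each). With Q140 it was 30.48 ± 1.19 CPM, 74.89 ± 3.92 CPM in Q140 x Msh3+/- and 115.5 ± 7.78 CPM in Q140 x Msh3-/- mice (SD, n = 8 each). The ranges by number of intact alleles did not overlap: 26.4 to 32.49 CPM with 2, 68.4 to 81.5 CPM with 1 and 103.2 to 126.4 CPM with 0. The counts thus sorted every library by its labelled Msh3 genotype, but in the direction opposite to a loss of RNA. A count over the whole gene does not show whether the product is functional, so the genotype names below are those of the labels, and every direction drawn for a Msh3 genotype rests on them. Htt (ENSMUSG00000029104; chromosome 5, 34761740 to 34912534, plus strand), the gene that carries the Q140 repeat, was at 227 ± 7.95 CPM in WT and 213 ± 11 CPM in Q140 mice.

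**Figure D1:**
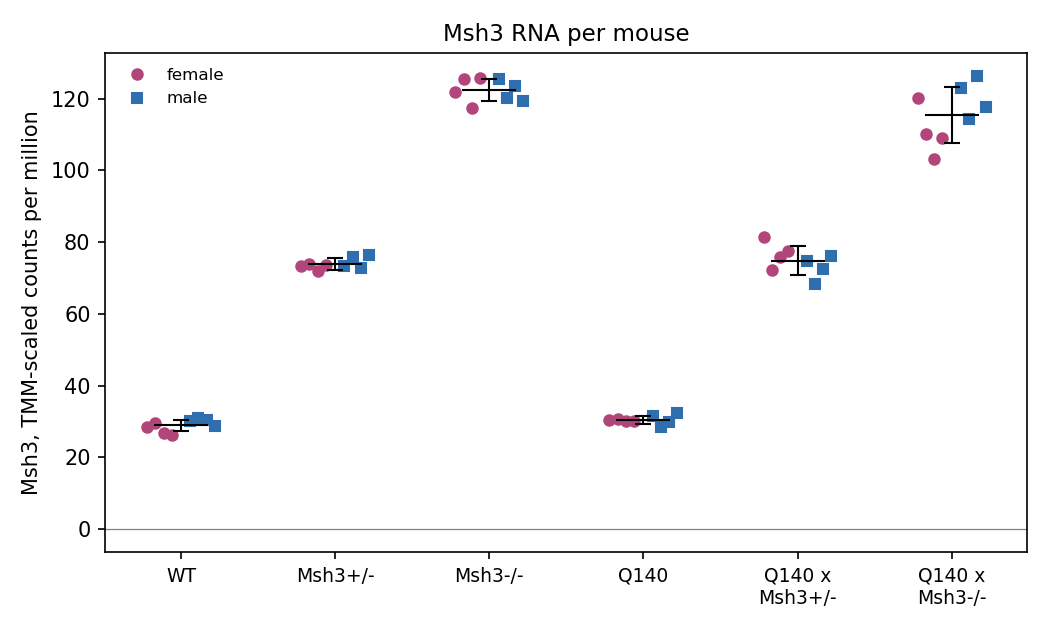
Msh3 RNA in TMM-scaled CPM (vertical axis) for each mouse of the 6 genotypes (horizontal axis). Circles are females, squares males, and bars the mean ± SD of 8 mice. The libraries with 2, 1 and 0 intact alleles by their labels lie in separate bands at 26.4 to 32.49, 68.4 to 81.5 and 103.2 to 126.4 CPM.

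Q140 mice differed from WT in genes that define the spiny projection neurons, the GABAergic output cells that make up most of the striatum. Of 28 spiny projection neuron identity genes, 26 fell and 1 rose. Pde10a, a cyclic nucleotide phosphodiesterase enriched in these cells, fell by 0.98 (SE 0.0457, adjusted p = 1.82e-23). Adcy5, the main striatal adenylyl cyclase, fell by 0.83 (SE 0.0392). Arpp21 fell by 0.85 (SE 0.0472), and Ppp1r1b, which encodes the dopamine signalling protein DARPP-32, fell by 0.77 (SE 0.0405). Scn4b, a sodium channel subunit, fell by 1.35 (SE 0.075). The camera test placed the list below other genes (adjusted p = 1.75e-35, and adjusted p = 0.00195 with an estimated correlation).

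Markers of the indirect pathway fell as a set, with 6 of 7 members lower (camera adjusted p = 3.94e-10, and adjusted p = 0.00291 with an estimated correlation). Penk, the enkephalin precursor, fell by 1.33 (SE 0.0539, adjusted p = 7.07e-25). Adora2a, an adenosine receptor gene, fell from 406.7 ± 40.1 CPM to 202.8 ± 19.4 CPM (SD, n = 8), Gpr6 by 0.75 (SE 0.0494) and Drd2, the D2 dopamine receptor, by 0.73 (SE 0.0428). Direct-pathway markers moved both ways, with 4 of 8 lower and 3 higher, and the list did not pass (camera adjusted p = 0.138). Drd1, the D1 dopamine receptor, fell by 0.71 (SE 0.0417) and Chrm4, the M4 muscarinic receptor, by 0.79 (SE 0.0443), while Isl1 and Eya1 rose by 0.25 (SE 0.0483) and 0.34 (SE 0.0781). Of 20 glutamate receptor, GABA receptor and potassium channel genes, 14 fell and 2 rose (camera adjusted p = 3.23e-09, and adjusted p = 0.00467 with an estimated correlation). Gabrd fell by 0.65 (SE 0.041), Kcnh4 by 0.97 (SE 0.0752) and Kcnq5 by 0.48 (SE 0.0375).

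The largest falls among adequately expressed genes were in Gpx6, a glutathione peroxidase (log2 fold change -3.27, SE 0.209), Sec14l3 (-2.50, SE 0.186), Abhd11os (-2.40, SE 0.148), Ddit4l (-2.39, SE 0.114) and Slc4a11 (-2.37, SE 0.151), followed by Gm9754 (-2.07), Phex (-1.96) and Vwa7 (-1.95). The largest rises were in Sfmbt2, a Polycomb-group gene (2.34, SE 0.139), Tmc3 (1.80, SE 0.142), Pcdh20 (1.36, SE 0.119), Dsg2 (1.33, SE 0.242), Ipcef1 (1.30), Rprm (1.25) and Cbx8, another Polycomb-group gene (1.18, SE 0.0928). Among 57 clustered protocadherins, cell adhesion genes expressed in combinations by single neurons, 30 rose and 7 fell (camera adjusted p = 5.04e-08, but adjusted p = 0.133 with an estimated correlation). Pcdhb3 rose by 0.97 (SE 0.0955), Pcdhb21 by 0.82 (SE 0.0771), Pcdhga2 by 0.74 (SE 0.063) and Pcdhb9 by 0.63 (SE 0.0573). Reads of such close paralogs can be split between them by the counting. Of 7 tested Hox and other developmental fate genes, 2 rose (camera adjusted p = 0.102). Onecut1, a homeobox gene, went from 7 counts over the 8 WT libraries to 1180 counts over the 8 Q140 libraries. This 159-fold difference had a 95% counting interval of 76.9 to 396, and Onecut2 rose by 0.48 (SE 0.0918). Counting intervals, here and below, cover the counting error of the pooled libraries alone, not variation between mice.

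Markers of other cell types were mostly lower as well, by small amounts. Of 12 endothelial and mural markers 10 fell, among them Pdgfrb by 0.29 (SE 0.0543) and Rgs5 by 0.27 (SE 0.0526) (camera adjusted p = 0.000299, but adjusted p = 0.146 with an estimated correlation). Of 12 microglia markers 6 fell, among them C1qb by 0.32 (SE 0.0738), and the camera adjusted p was 0.00786, but 0.489 as an adjusted p with an estimated correlation. Of 12 astrocyte markers 5 fell, among them Slc1a2 by 0.24 (SE 0.0409), and of 12 interneuron markers 5 fell, among them Nos1 by 0.26 (SE 0.0348). Their camera adjusted p-values of 0.031 and 0.03 both became an adjusted p of 0.353 with an estimated correlation. Of 13 mature oligodendrocyte markers 5 fell, among them Mobp by 0.36 (SE 0.0683), without a list call (camera adjusted p = 0.121). With total counts in place of TMM scaling, which was chosen after seeing the data, 1 astrocyte and 1 oligodendrocyte marker passed as higher. Oligodendrocyte precursor, choroid plexus and ependymal, cortical, thalamic and hypothalamic, and disease-associated microglia lists did not pass, with camera adjusted p-values of 0.416, 0.814, 0.945, 0.182 and 0.165.

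Of 15 mismatch repair genes other than Msh3, 6 rose and 0 fell, among them Mlh3 by 0.21 (SE 0.0322) and Msh6 by 0.19 (SE 0.0484). The camera adjusted p was 0.0493, but 0.169 as an adjusted p with an estimated correlation. Of 12 heat shock and chaperone genes 4 rose and 0 fell, with Hspa8 higher by 0.34 (SE 0.0593), without a list call (camera adjusted p = 0.0649). Cholesterol synthesis genes (4 up and 2 down of 18), p53 targets (2 up and 2 down of 12), oxidative phosphorylation genes (15 up and 6 down of 82), interferon-response genes (1 up and 5 down of 14) and immediate early genes (2 down of 14) moved without list calls, with camera adjusted p-values of 0.167, 0.647, 0.157, 0.338 and 0.369. These counts depended on the scaling. With total counts they were 41 up and 1 down for oxidative phosphorylation, 9 up and 1 down for cholesterol synthesis, 4 up and 1 down for p53 targets and 1 up and 2 down for interferon response (1 up and 0 down with limma on FPKM). The genes near Msh3 (6 up and 8 down of 29) and near Htt (5 up and 8 down of 24) did not pass as lists (camera adjusted p = 0.556 and 0.325), nor did all tested genes within 5 Mb of Msh3 (11 up and 13 down of 59, camera adjusted p = 0.688) or of Htt (35 up and 26 down of 150, camera adjusted p = 0.616). With total counts these 4 lists had 9 up and 6 down, 9 up and 4 down, 17 up and 10 down, and 56 up and 19 down. Adjusted over the list alone, the counts for the identity, indirect-pathway, channel and protocadherin lists were 26 down and 1 up, 6 down, 14 down and 2 up, and 33 up and 9 down.

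In all, 6506 of 19714 genes passed the threshold in Q140 minus WT, 3358 higher and 3148 lower, and 322 of them differed at least 2-fold. For 100 of the 108 genes named by the rule, all 8 Q140 mice lay on the called side of the WT mean. The genes were named from these same mice, which favours such agreement. The split into higher and lower calls depended on the scaling: it was 5773 and 2064 with total counts, and 5821 and 2065 with limma on the deposited FPKM values. With the prefix of the sample names as a term, chosen after seeing the data, 3336 genes passed, 1521 higher and 1815 lower.

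Without Q140, loss of Msh3 alleles changed few genes, and these lay on chromosome 13. In Msh3-/- minus WT, 9 genes passed. Msh3 was higher by 2.08 (SE 0.0354, adjusted p = 5.17e-45). F2r, the thrombin receptor, 3.25 Mb from Msh3, was higher by 0.89 (SE 0.0975). Rasgrf2 (chromosome 13, 91880400 to 92131656) fell by 1.31 (SE 0.129), AW495222 fell by 1.17 (SE 0.147), Cmya5 (93040713 to 93144724) by 0.96 (SE 0.0688), Ankrd34b by 0.34 (SE 0.0554), Sv2c by 0.27 (SE 0.0426), Map1b, 7.07 Mb away, by 0.21 (SE 0.0443) and Col4a3bp by 0.20 (SE 0.0306). All 9 differed from the WT mean in the called direction in all 8 Msh3-/- mice, the same mice that gave the calls. In Msh3+/- minus WT only Msh3 (1.35, SE 0.035) and F2r (0.52, SE 0.098, adjusted p = 0.0219) passed. None of the spiny projection neuron lists had a member past the threshold in either contrast. In Msh3-/- minus WT camera placed the genes near Msh3 low (adjusted p = 3.73e-08, and adjusted p = 0.000665 with an estimated correlation). Without genes within 5 Mb of Msh3 or Htt, an alternative chosen after seeing the data, both contrasts called 0 genes in edgeR. At an unadjusted p under 0.05 there were 937 genes in Msh3+/- minus WT and 1187 in Msh3-/- minus WT among all genes tested, and DESeq2 called 5 in the first. With the name prefix as a term edgeR called 1 gene in the first and 5 in the second.

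In Q140 x Msh3-/- minus Q140, genes of the spiny projection neuron lists moved opposite to the Q140 effect. Of the 28 spiny projection neuron identity genes 26 were higher and 1 lower than in Q140 mice (camera adjusted p = 2.56e-34, and adjusted p = 0.00128 with an estimated correlation), and all 7 indirect-pathway markers were higher (camera adjusted p = 9.23e-12, and adjusted p = 0.00128 with an estimated correlation). Penk was higher by 0.76 (SE 0.0534, adjusted p = 6.85e-15), Adora2a by 0.64 (SE 0.0645), Chrm4 by 0.54 (SE 0.0443), Adcy5 by 0.52 (SE 0.0391), Pde10a by 0.51 (SE 0.0454), Ppp1r1b by 0.44 (SE 0.0404), Drd1 by 0.43 (SE 0.0416) and Drd2 by 0.43 (SE 0.0427). Of 8 direct-pathway markers 4 rose, among them Slc35d3 (0.23, SE 0.0527) and Pdyn, the dynorphin precursor (0.25, SE 0.0757), with a camera adjusted p of 0.0033, but 0.0717 as an adjusted p with an estimated correlation. Of the 20 receptor and channel genes 10 rose and 0 fell, led by Gabrd (0.48, SE 0.041), Kcnip2 (0.44, SE 0.0506), Kcnq5 (0.34, SE 0.0375) and Kcna4 (0.26, SE 0.0325) (camera adjusted p = 5.82e-10, and adjusted p = 0.00292 with an estimated correlation).

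Among genes with a mean log2 CPM of at least 1, the largest rises were in Gpx6 (2.20, SE 0.212), Msh3 itself (1.92, SE 0.0351), Abhd11os (1.88, SE 0.148), Fst (1.71, SE 0.148), Sec14l3 (1.49, SE 0.188), Ddit4l (1.46, SE 0.114), Slc4a11 (1.38, SE 0.152) and Mas1 (1.37, SE 0.123). The largest falls among these were in Sfmbt2 (-1.81, SE 0.135), Emx2os (-0.91, SE 0.121), BC030499 (-0.86), Pcdh20 (-0.81, SE 0.116), Vwa5b2 (-0.79), Onecut2 (-0.73, SE 0.0924), Tpx2 (-0.70) and Slc5a5 (-0.69). Onecut1, below that level, had 24 counts over the 8 Q140 x Msh3-/- libraries against 1180 in Q140, a 47-fold difference with a 95% counting interval of 31.5 to 73.7. The developmental fate list was lower (2 of 7 members, camera adjusted p = 0.0033, and adjusted p = 0.0141 with an estimated correlation). Of 57 clustered protocadherins 20 fell and 2 rose, among them Pcdhb3 (-0.50, SE 0.0936) and Pcdhb22 (-0.49, SE 0.0685), with a camera adjusted p of 1.83e-06, but 0.124 as an adjusted p with an estimated correlation. Mismatch repair genes were lower in 4 of 15 cases, with Mlh3 at -0.19 (SE 0.0322), and the camera adjusted p was 0.00834, but 0.057 as an adjusted p with an estimated correlation. Microglia markers were higher in 3 of 12 cases and immediate early genes in 3 of 14, with camera adjusted p-values of 0.00532 and 0.003 that both became an adjusted p of 0.493 with an estimated correlation. Of 12 endothelial and mural markers 2 were higher, Pdgfrb by 0.19 (SE 0.0544) and Cdh5 by 0.21 (SE 0.0714), without a list call (camera adjusted p = 0.054). Astrocyte (of 12), disease-associated microglia (of 12), interneuron (of 12), cortical (of 9) and thalamic and hypothalamic (of 5) lists had 1 member higher each, with camera adjusted p-values of 0.117, 0.117, 0.387, 0.278 and 0.396. The genes near Msh3 were again lower (6 of 29, with 1 higher), led by Cmya5 (-0.68, SE 0.0688) and Rasgrf2 (-0.60, SE 0.127), and the camera adjusted p of 0.0153 became an adjusted p of 0.124 with an estimated correlation. In total 3217 genes passed, 1725 higher and 1492 lower, and with total counts 1283 higher and 2869 lower. With the prefix of the sample names as a term, chosen after seeing the data, 637 passed. For 59 of the 69 named genes all 8 mice lay on the called side of the Q140 mean, and these genes were again named from the same mice.

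In Q140 x Msh3+/- minus Q140, some members of the spiny projection neuron lists were higher, but no list kept its call with an estimated correlation. Of the identity genes, 8 of 28 were higher and 0 lower, 17 when adjusted over the list alone, with a camera adjusted p of 1.1e-16, but 0.0594 as an adjusted p with an estimated correlation. Adcy5 was higher by 0.24 (SE 0.039, adjusted p = 0.000224), Rgs9 by 0.27 (SE 0.0493), Rasgrp2 by 0.25 (SE 0.0495) and Ryr1 by 0.70 (SE 0.127). Of 7 indirect-pathway markers 3 were higher, with Adora2a at 0.35 (SE 0.0644) and Penk at 0.27 (SE 0.0531), and of 8 direct-pathway markers 2 were higher, with Chrm4 at 0.24 (SE 0.0444) and Drd1 at 0.19 (SE 0.0416). Their camera adjusted p-values of 7.87e-07 and 0.00655 became adjusted p-values of 0.0529 and 0.147 with an estimated correlation. Among genes with a mean log2 CPM of at least 1, and beside Msh3 (1.30, SE 0.0348), the largest rises were in Fst (1.20, SE 0.15), Abhd11os (1.15, SE 0.151), Gpx6 (1.12, SE 0.221), Gm9754 (0.94), Vwa7 (0.93) and Sec14l3 (0.91, SE 0.191). The largest falls among these were in Sfmbt2 (-0.74, SE 0.129), Emx2 (-0.51, SE 0.0799), Emx2os (-0.51, SE 0.119), Pcdh20 (-0.43, SE 0.114) and Gng4 (-0.41, SE 0.0994). The channel (2 of 20 higher), protocadherin (0 of 57), heat shock (0 of 12), developmental fate (1 of 7 lower) and Msh3-neighbour (1 of 29 lower) lists had camera adjusted p-values of 0.00209, 0.000173, 0.000916, 0.0272 and 0.0374, which became adjusted p-values of 0.211, 0.254, 0.254, 0.1 and 0.239 with an estimated correlation.

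In that contrast 260 genes passed, 166 higher and 94 lower, and the number moved with the libraries used. It was 154 without the 4 libraries that stood apart on the first residual component, a choice made after seeing the data. With the prefix of the sample names as a term, also chosen after seeing the data, it was 7, and with the prefix as a random effect in limma-voom it was 262. It was 136 without Q140 x Msh3+/- mouse F1, 124 without Q140 x Msh3+/- mouse F4, 153, 122 and 172 without Q140 mice F2, F3 and M3, and 481 without Q140 mouse M2. Between the crosses, Q140 x Msh3-/- minus Q140 x Msh3+/-, 637 genes passed, 452 higher and 185 lower (252 and 679 with total counts, 212 and 65 with the name prefix as a term), including 17 of the 28 identity genes, all higher (camera adjusted p = 7.6e-30, and adjusted p = 0.00213 with an estimated correlation).

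The Q140 effect was also measured against mice of the same Msh3 genotype, which share no library with Q140 minus WT. On the Msh3+/- background 4247 genes passed, 2120 higher and 2127 lower (4507 and 1351 with total counts, 1122 and 1385 with the name prefix as a term), and 25 of 28 identity genes fell. On the Msh3-/- background 1549 passed, 791 higher and 758 lower (1252 and 623 with total counts, 217 and 379 with the name prefix as a term), and 19 of 28 identity genes fell (camera adjusted p = 7.5e-31, and adjusted p = 0.00496 with an estimated correlation). The difference itself was tested as an interaction. For Msh3-/-, 1213 genes passed, 806 higher and 407 lower (537 and 1194 with total counts; 219 and 24 with the name prefix as a term), where higher means less negative or more positive with Q140 on the Msh3-/- background. They included 24 of 28 identity genes, all higher, with Scn4b at 0.80 (SE 0.104), Arpp21 at 0.51 (SE 0.0663), Adcy5 at 0.51 (SE 0.0552) and Pde10a at 0.50 (SE 0.0641). The indirect-pathway marker Penk was higher by 0.81 (SE 0.0751, adjusted p = 2.9e-10) and the direct-pathway marker Chrm4 by 0.53 (SE 0.0622). Gpx6 (2.13, SE 0.275), Abhd11os (1.90, SE 0.198), Fst (1.69, SE 0.201), Ddit4l (1.54, SE 0.154) and Chrna4, a nicotinic receptor subunit (1.13, SE 0.119), had large positive interactions. Sfmbt2 (-1.77, SE 0.198), BC030499 (-1.14), Tpx2 (-1.06, SE 0.18), Emx2os (-1.04) and Onecut2 (-0.92, SE 0.13) had large negative interactions. For Msh3+/-, 3 genes passed: Fst (1.18, SE 0.202), Abhd11os (1.13, SE 0.2) and Nptx1 (0.54, SE 0.101). DESeq2 called 64 genes in that interaction, and edgeR with the name prefix as a term 0. The indirect-pathway list was higher in it with 0 of 7 members past the threshold (camera adjusted p = 3.29e-07, and adjusted p = 0.0401 with an estimated correlation), while the identity list had a camera adjusted p of 9.06e-09, but 0.472 as an adjusted p with an estimated correlation.

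**Figure D2:**
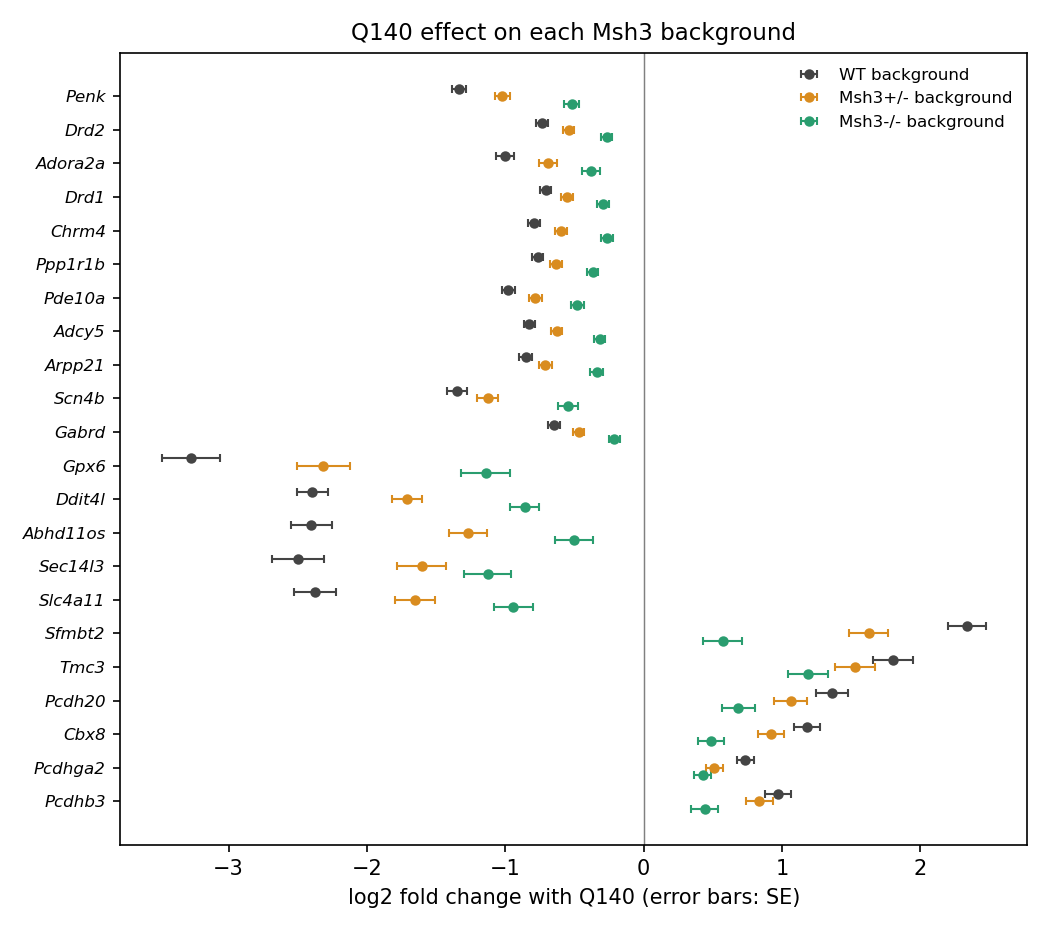
Log2 fold change with Q140 (horizontal axis; points are estimates, bars the SE) for 22 genes (vertical axis) on the WT, Msh3+/- and Msh3-/- backgrounds, each against mice of the same Msh3 genotype (n = 8 per group). Penk, at -1.33 on the WT background, and the other spiny projection neuron genes plotted lie nearer to 0 on the Msh3-/- background.

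Reversal was then quantified. Of the 6506 genes called in Q140 minus WT, 2887 (44.4%) also passed with the opposite sign in Q140 x Msh3-/- minus Q140, and 6 passed with the same sign. The reversed genes comprised 1350 that had risen and 1537 that had fallen in Q140, and this balance depended on the scaling: it was 2712 and 1085 with total counts, and 2715 and 1067 with limma on FPKM. Simulated data with no change between the Q140 groups gave a mean of 0, and independent lists of these sizes would share 529.6 with opposite signs. The simulated genes were drawn independently, without structure shared across genes, so that mean of 0 may be too low. Other splits of the libraries of Q140 x Msh3-/- minus Q140 called up to 1116 genes. With the Q140 mice split, so that 4 served each contrast, the reversed share averaged 29.7% when the contrasts used different mice and 33.2% when they used the same mice. The covariance of the fold changes was -0.07067 with all mice, against -0.0171 in the simulated data. With split Q140 mice it was -0.0888 when the contrasts used the same mice and -0.0561 when they used different mice. For Q140 x Msh3+/-, 242 genes (3.72%) were reversed and 1 passed with the same sign. The simulated mean was 0.1, and independent lists would share 42.52 with opposite signs. With the name prefix as a term the 2 reversal counts were 590 and 6, and with it as a random effect 3008 and 244. For Q140 x Msh3+/- the count was 144 without the 4 libraries that stood apart, 145, 118 and 160 without Q140 mice F2, F3 and M3, and 445 without Q140 mouse M2. With split Q140 mice 0.521% were reversed with different and 0.514% with the same mice, where a mean of 27 genes passed in Q140 x Msh3+/- minus Q140. The covariance for this cross was -0.0266 with different and -0.0592 with the same mice. Sharing the Q140 mice thus did add to the opposite movement.

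The cross-fitted signature score, in which the mice that chose the genes were never scored with them, gave the size of the reversal per mouse. It was 0.365 ± 0.0423 in Q140, 0.268 ± 0.0422 in Q140 x Msh3+/- and 0.146 ± 0.0391 in Q140 x Msh3-/- mice (SD, n = 8), on a scale where the WT mean is 0 and its SD 0.0122. All 8 Q140 x Msh3-/- mice (0.103 to 0.196) lay below all 8 Q140 mice (0.269 to 0.41) and above all WT mice (exact permutation p = 0.000155 against Q140, the smallest possible, adjusted p = 0.000249). Q140 x Msh3+/- mice ranged from 0.206 to 0.308 and were below Q140 (exact permutation p = 0.000932, adjusted p = 0.00124) and above Q140 x Msh3-/- (exact permutation p = 0.000155, adjusted p = 0.000249). The share reversed was 60% (95% interval 51.7 to 67.3) for Q140 x Msh3-/- and 26.5% (16.6 to 35.6) for Q140 x Msh3+/-. Without Q140, Msh3+/- and Msh3-/- scores differed from WT by -0.00605 and -0.00901, which did not pass (exact permutation p = 0.508 and 0.252, n = 8). The Q140 x Msh3+/- share was 37.2% in females alone (95% interval 25.4 to 45.7, exact permutation p = 0.0286, n = 4, the smallest possible). In males alone it was 14.5% (-0.859 to 23.1) and did not pass (exact permutation p = 0.143, n = 4). That male value leans on Q140 mouse M2, at 0.2689, below all Q140 x Msh3+/- males (0.2866 to 0.3045). The other Q140 males scored 0.3592 to 0.39, above all of these. The male share was not computed without Q140 mouse M2.

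**Figure D3:**
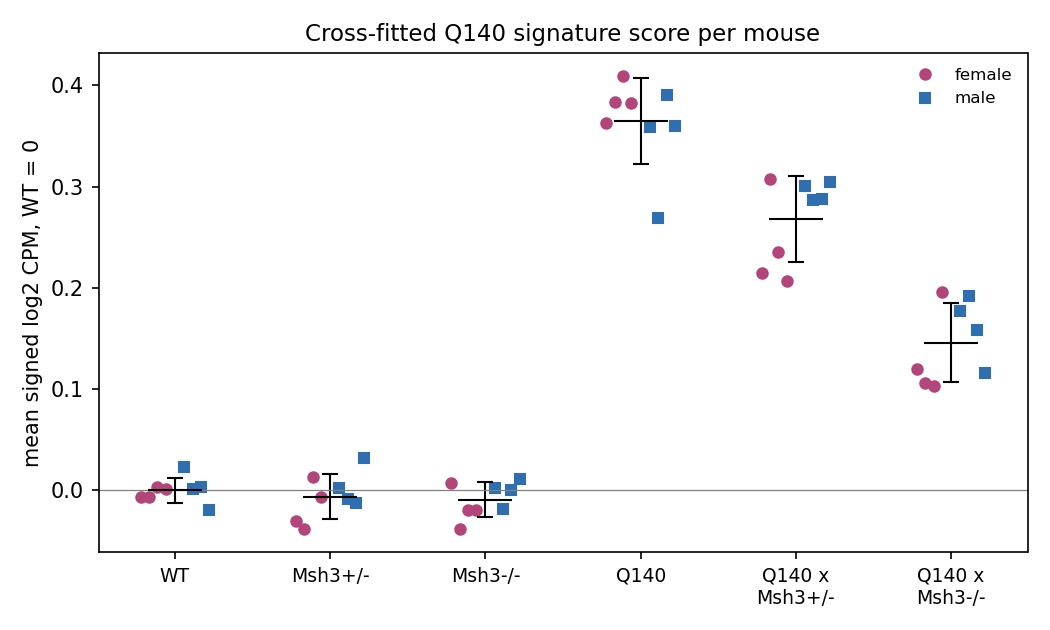
Cross-fitted Q140 signature score (vertical axis, mean signed log2 CPM with the WT mean at 0) for each mouse of the 6 genotypes (horizontal axis). Circles are females, squares males, and bars the mean ± SD of 8 mice. The means are 0.365 in Q140, 0.268 in Q140 x Msh3+/- and 0.146 in Q140 x Msh3-/- mice.

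No gene passed the test of a sex difference in edgeR, either for the Q140 effect or for Q140 x Msh3-/- minus Q140. With DESeq2 size factors in edgeR the counts were also 0, and DESeq2 itself was not run on these differences. At an unadjusted p under 0.05 there were 677 and 762 of 20455 genes. Within the sexes, Q140 minus WT called 4400 genes in females and 3086 in males, and Q140 x Msh3-/- minus Q140 called 1973 and 453. The males include Q140 mouse M2, whose score was the lowest of the Q140 mice. Its part in the male values was not tested. The score differences between females and males, 0.0441 for Q140 minus WT, -0.0942 for Q140 x Msh3+/- minus Q140 and -0.0697 for Q140 x Msh3-/- minus Q140, did not pass either (exact permutation, adjusted p = 0.128, 0.066 and 0.128 over 3 comparisons, n = 4 per sex and group).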

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

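The tests of explanations in this part were chosen after the results were seen, except that of nuclear noncoding RNA. The interaction tests were planned, and the number of other splits was settled after shorter runs had been seen. Of 36 groups of libraries checked for a value far from its fellows, 4 had one, and chance gives about 1 in 20. Htt was at 238 CPM in Msh3-/- mouse M3, above the other 7 mice of its group. The signature score of Q140 mouse M2 was 0.269, against 0.359 to 0.41 in the other 7. On the first component of the residuals, Q140 x Msh3+/- mouse F1 lay at 44.9 and Q140 x Msh3-/- mouse M1 at 41.2. The Q140 effect differed between Msh3 backgrounds, by the interaction test, in 3 genes for Msh3+/- and in 1213 genes for Msh3-/-.

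Msh3 RNA rose with each allele labelled as lost, and the other 8 genes called in Msh3-/- minus WT lay on chromosome 13. A wrong Msh3 genotype on single libraries is argued against, since 0 of 48 libraries had Msh3 within the range of libraries labelled with another number of intact alleles. An exchange of the labels of whole groups stays open and was not tested. If the groups with 2 and 0 intact alleles were exchanged, the score of 0.146 would belong to Q140 mice with both alleles intact and that of 0.365 to those with none, which would turn the direction of the reversal round. The grouping of the called genes near Msh3 had a Fisher's exact p of 1.19e-17, and the same signs appeared in Q140 x Msh3-/- minus Q140. DNA around Msh3 that came with the altered allele, from another strain or from the targeting itself, is therefore a candidate explanation for the neighbouring genes. What the RNA counted over Msh3 consists of stays open, because counts per gene do not show which exons were read.

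Q140 mouse F1, labelled female, had Xist at 1.44 CPM, against 1490 to 2410 CPM in the other 23 females. A male library under a female label is argued against, since 0 of 4 Y-linked genes reached the male range (Ddx3y at 0.0202 CPM). A loss of nuclear noncoding RNA is argued against, since the median log2 difference of 8 such RNAs from the other Q140 females was 0.0767. All 4 of the X-linked genes tested that escape inactivation were within the male range and below every other female, so that a single X chromosome in this mouse may be the source. The genes were chosen after Xist was seen, and no biological explanation in the design was tested.

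The fall of the spiny projection neuron identity genes in Q140 was weighed against a changed tissue makeup. A lower share of these neurons would raise the markers of other cell types, if those cells were themselves unchanged. The mean of 58 such markers instead differed by -0.161 on the log2 scale (exact permutation p = 0.000155, n = 8), and by -0.0921 with total counts (exact permutation p = 0.011, n = 8). A fall of these markers within their own cells could hide such a rise, and cells were not counted. A lower share is therefore not excluded. Differing amounts of cortical tissue are argued against as the whole cause. The mean of 9 cortical markers differed by only -0.035 between Q140 and WT (exact permutation p = 0.838, n = 8). As a covariate this mean could therefore hardly move the contrast. It took up 44 genes outside the marker list, while 26 identity genes still fell and their median went from -0.523 to -0.521. The number of genes asked to follow the covariate was lowered from over 100 to 10 after the count of 50 had been seen. An effect of the Q140 allele on transcription within these neurons also stays open, as a hypothesis.

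Other splits of the same libraries were fitted to ask whether chance can be excluded, with 100 splits per result, the real one included. Splits that put each sex on a side of its own were not drawn. Shorter runs with fewer splits had been made first. By the share of splits that reached the real count they led to the same conclusions. Their highest other counts differed from these, and were much higher in some shorter runs for the contrasts given below with a highest other of 1. The highest values below therefore depend on the splits drawn. Fits used only the libraries compared, so the real counts differ from those of the fit of all 48. Only the real split reached its count for Q140 minus WT (6471 genes, highest other split 1815) and Msh3-/- minus WT (9, highest other 6). So it was for Q140 x Msh3+/- minus Q140 (181, highest other 1) and Q140 x Msh3-/- minus Q140 (3257, highest other 1116). Q140 x Msh3-/- minus Q140 x Msh3+/- (526, highest other 113) was alike. The same holds for Q140 x Msh3+/- minus Msh3+/- (3743, highest other 1), Q140 x Msh3-/- minus Msh3-/- (1304, highest other 570) and the Msh3-/- interaction (1250, highest other 8). That is 1 split in 100, the smallest share that 100 splits can give. Apart from Msh3-/- minus WT, chance is argued against for these counts at that level, but not excluded. For the Msh3+/- interaction, too, only the real split reached its count (3, highest other 2). That margin, like the 9 against 6 in Msh3-/- minus WT, is too narrow to argue against chance, since the highest values depend on the splits drawn. Nor is chance argued against for the count in Msh3+/- minus WT. There 9 of 100 splits, the real one included, gave at least the real count of 1. The highest of them gave 30, several times the real count, which points to some structure of these samples that was not identified. The called gene itself was Msh3, at 71.95 to 76.53 CPM in Msh3+/- and 26.4 to 30.92 CPM in WT mice, so this does not put its difference in doubt. Shared prefixes of the sample names are a candidate for such structure: after removal of genotype and sex, 31 pairs of libraries with the same prefix in different groups correlated at 0.0334 on average and all other pairs at -0.0225, a mean that includes pairs within a group, which the fit itself makes negative. The plate's well column is another candidate. It accounted for 50.2% of the variance of the third residual component, which held 4.7% of the residual variance. The splits were drawn neither within prefixes nor within well columns, and neither candidate was tested as the source. For the sex differences the splits decide nothing, since a real count of 0 is reached by all 100 splits whatever the data, and the highest others were 14 for the Q140 effect and 28 for Q140 x Msh3-/- minus Q140.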

How the results depend on the processing

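Total counts in place of TMM, the data without 4 libraries apart, without Q140 mouse F1, without genes near Msh3 or Htt, and the name prefix as a term or a random effect were chosen after seeing the data. Named genes and lists were not followed with single mice left out, Q140 mouse F1 included, nor at an adjusted p under 0.10. Leaving out genes near Msh3 or Htt kept the same fit, so it could not change a sign. Of the named genes 1 changed sign under the other alternatives: Cdh5, Q140 by Msh3-/- interaction, went from 0.3327 to -0.02521 (adjusted p = 0.973) with the name prefix as a term. The balance of higher and lower calls turned with total counts: the share higher went from 53.6% to 30.9% for Q140 x Msh3-/- minus Q140, from 71% to 27.1% for Q140 x Msh3-/- minus Q140 x Msh3+/- and from 66.4% to 31% for the Msh3-/- interaction, and limma on FPKM gave 30.4%, 25.8% and 29.6%. Over 3575 combinations of a named gene and a setting, 3321 kept their side of the threshold, 253 fell short of it and 1 reversed; of 369 combinations of a list and a setting, 327 stayed within 1.5 times and 42 moved. The cause of these changes was not tested. For Msh3+/- minus WT (2 genes) the count was 1 without the 2 WT mice of another name prefix, 1 with only the groups of the contrast, 5 with DESeq2, 4 with the prefix as a random effect and 0 without genes within 5 Mb of Msh3 or Htt. Msh3-/- minus WT (9) gave 0 without those genes. Of the 9, 8 were removed with them, Msh3 included, and for Map1b, Msh3-/- minus WT, which lies farther away, the fold change stayed at -0.21 (SE 0.0443) while the adjusted p went from 0.0331 to 0.295 as the adjustment ran over fewer genes, without the smallest p-values. Q140 x Msh3+/- minus Q140 (260) gave 422 with the well column added, 154 without the 4 libraries, 449 with DESeq2 and 529 at an adjusted p under 0.10, and the matching reversal count (242) gave 389, 144, 412 and 490. Q140 x Msh3-/- minus Q140 x Msh3+/- (637) gave 971 at an adjusted p under 0.10. The Msh3+/- interaction (3) gave 10 with the well column, 5 with total counts, 10 with limma on FPKM, 64 with DESeq2, 26 at an adjusted p under 0.10 and 5 without Q140 mouse F1. The score share for Q140 x Msh3+/- was 14.5% in males alone and no longer passed, a value that leans on Q140 mouse M2.

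The name prefix as a term changed the most: of 266 named genes 149 kept their call and 116 fell short. All 10 contrasts and both reversal counts moved: Q140 minus WT from 6506 to 3336, Msh3+/- minus WT from 2 to 1, Msh3-/- minus WT from 9 to 5, Q140 x Msh3+/- minus Q140 from 260 to 7, Q140 x Msh3-/- minus Q140 from 3217 to 637 and Q140 x Msh3-/- minus Q140 x Msh3+/- from 637 to 277. Q140 x Msh3+/- minus Msh3+/- went from 4247 to 2507, Q140 x Msh3-/- minus Msh3-/- from 1549 to 596, the interactions from 3 to 0 and from 1213 to 243, and the reversal counts from 2887 to 590 and from 242 to 6. That fit kept 15 residual degrees of freedom against 41 and took up 15 libraries, and whether the loss comes from this or from differences between prefixes was not tested. With the prefix as a random effect (correlation within prefix 0.119) 262 of the 266 kept their call, and of the 10 contrasts only Msh3+/- minus WT moved. The score was not run with the prefix.

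Leaving out each mouse in turn gave 6038 to 6575 genes for Q140 minus WT, 8 to 9 for Msh3-/- minus WT, 122 to 481 for Q140 x Msh3+/- minus Q140 and 2696 to 3369 for Q140 x Msh3-/- minus Q140. With each of the 8 Q140 mice left out, and no other mouse, the reversal counts ranged from 2459 to 3059 for Q140 x Msh3-/- and from 118 to 445 for Q140 x Msh3+/-, among these lowest without Q140 mouse F3 and highest without Q140 mouse M2. With the replicate number as a block, Q140 minus WT gave 6526 genes, Q140 x Msh3+/- minus Q140 269, Q140 x Msh3-/- minus Q140 3224 and the Msh3-/- interaction 1199. The labels do not say that the numbers pair the mice, and the highest mean correlation within any of the 8 numbers was -0.000303. Of 48 libraries, 17 correlated best with their own number among the 4 of their sex, against a mean of 12 with permuted numbers (permutation p = 0.128). The block moved none of the counts by over 1.5 times. Changes of 0.25 on the log2 scale were recovered in 35 of 100 simulated genes for the Msh3-/- interaction, none of them low-count genes. Smaller changes, and changes in low-count genes, could thus be missed at this depth and n.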

Other observations

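Some Q140 changes of at least 2-fold were also at least 2-fold on the Msh3-/- background, most of them smaller there. Of the 322 genes changed at least 2-fold in Q140 minus WT, 27 also passed the edgeR threshold and were changed at least 2-fold in the same direction in Q140 x Msh3-/- minus Msh3-/-. The change was smaller on the Msh3-/- background in 23 of the 27, and 8 of these passed the Msh3-/- interaction test. Most of the 27 had a mean log2 CPM below 1, the floor of the naming rule, with the lowest at -2.38. The genes named next lie above that floor. Gpx6 went from a fall of 3.27 (SE 0.209) to 1.14 (SE 0.18) and Sec14l3 from 2.50 (SE 0.186) to 1.13 (SE 0.171), and both passed that test. Among those that shrank less, Rprm, a p53-induced cell cycle inhibitor, rose by 1.25 (SE 0.115) on the WT background and by 1.07 (SE 0.116) on the Msh3-/- background, and Tmc3 rose by 1.80 (SE 0.142) and 1.19 (SE 0.144). Phex, a membrane endopeptidase, fell by 1.96 (SE 0.225) and by 1.30 (SE 0.217). Cpne9, which was chosen after its values were seen, fell by 1.86 (SE 0.124) and by 1.21 (SE 0.12).

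The tests below were chosen after the results were seen. Gm2420, also chosen after its values were seen, went from 14 counts over the 8 WT libraries to 366 over the 8 Q140 libraries, a 24.6-fold difference (95% counting interval 14.5 to 45.5), and lies within 5 Mb of Htt. DNA around Htt carried along with the Q140 allele is argued against as the source of the set, since 26 of the 27 lie on chromosomes other than that of Htt. For the 1 gene within 5 Mb, Gm2420, it could be the source and cannot be told apart from an effect of the allele, with too few genes to decide (Fisher's exact p = 0.161). A second hypothesis was that each Msh3 allele lost lowers the score by the same amount. The Q140 x Msh3+/- mean lay 0.0127 above the midpoint of the other Q140 groups (95% bootstrap interval -0.021 to 0.0455), against a step of 0.109 per allele. By sex the 2 steps were -0.0496 (exact permutation p = 0.143, n = 4) and -0.134 in males, and -0.144 and -0.11 in females, and the first step did not pass as different between the sexes (exact permutation, adjusted p = 0.066). The first male step leans on Q140 mouse M2, whose score of 0.269 was the lowest of the Q140 mice. Whether the steps are equal within each sex was not tested.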
